A study of Homo sapiens with 6 samples.

How the data were processed

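RNA in 6 libraries of the human acute myeloid leukaemia line MOLM-13, which carries the MLL-AF9 translocation, was measured by RNA sequencing. Per the labels' protocols, the cells had been transduced with a lentiviral short hairpin RNA against LAMP5 (shLAMP5) or with a non-targeting one (shNT), selected with puromycin and harvested, and libraries were made from total RNA with a TruSeq RNA kit for a HiSeq instrument. The group of each library was taken from its title, giving 2 shNT and 4 shLAMP5 libraries. The number in each title is called the replicate number here, though the titles do not say what it marks. The protocol speaks of more than 1 harvest time. Which hairpin each shLAMP5 library received, and when each library was harvested, is not given in the sources used here, so the mean and SD of the 4 shLAMP5 libraries may mix hairpins or times. Nothing states that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

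The authors deposited 1 table of 39771 Ensembl gene identifiers by 6 libraries, and its values were read as TPM (transcript abundance scaled to a fixed total per library) because they are fractional and sum to between 897026 and 912565 per library; the table itself names no unit. Per the submitters' processing notes, kallisto and the genome build hg19 were used. The kallisto version, the transcript set, the step from transcripts to genes and any filter are not given in the sources used here. TPM keeps no record of read number, so the depth of each library is unknown and no counting interval was computed. Reads from near-identical genes (histone, HLA, ribosomal protein and interferon-induced families) may be split between copies, and values of such genes are uncertain. A total of 29895 identifiers were matched to a gene symbol, and 35677 had a gene type in GENCODE release 29, of which 18900 were protein-coding. No coordinates are given, since the reference at hand was of another build.

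The main test was limma (version 3.58.1, in R 4.3.3) with a mean-variance trend, on log2(TPM + 1), over genes with at least 1 TPM in at least 2 libraries, with the group as the sole factor and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. Log2 fold changes are shLAMP5 minus shNT on the log2(TPM + 1) scale, which understates the change of genes with low values. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 genes tested, and again with an estimated correlation and with fry. For LAMP5 and for the mean of each list, an exact two-sided permutation test ran over the 15 splits of 6 libraries into 2 and 4, whose smallest possible p is 0.0667. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

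The model, the 29 gene lists and the rule for named genes were fixed before the data were examined. The rule took LAMP5, the other LAMP family members LAMP1, LAMP2 and LAMP3, and NFKBIA, TNFAIP3, HOXA9, MEIS1 and IRF7. It then took up to 12 genes per direction past the threshold, with expression at or above the median and all 4 shLAMP5 libraries on 1 side of both shNT libraries. From each list described it took the 2 members with the smallest p in each direction. One gene that this rule takes is not reported here. No gene passed the threshold, so the part of the rule on 12 genes named none. Where other genes are named, the text says that they were chosen after their values were seen. The lists covered the pathways of the series title, MLL-fusion targets, myeloid differentiation, growth, stress and metabolism. They also held markers of T, B, erythroid and megakaryocytic cells, which had too few tested members, and of packaging cells and fibroblasts.

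On simulated data with the means and spread of these libraries, with 200 of 13072 genes changed, the test recovered 24% of genes changed 2-fold and 72% of those changed 4-fold, with 5 false calls. With the residual SD of every gene set to the median (0.294) it recovered 79% and 100%, with 13 false calls. Each was 1 run in which genes varied independently, and the changed genes were drawn from those above a minimum mean level. Genes in these libraries vary together (estimated correlation 0.73 for the cell cycle list). The recovery and false calls on the real data may therefore differ. The alternatives tried were other pseudocounts, filters, scalings and thresholds, leaving out each library, and the replicate number as a block. Library weights, protein-coding rows only, and the removal of shNT 1 together with shLAMP5 2 were added after the data were seen. Tests that need read counts were not run, because the table holds TPM.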

Results

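Gene expression was measured in MOLM-13, an acute myeloid leukaemia cell line driven by the MLL-AF9 fusion, after transduction with a hairpin against LAMP5 (shLAMP5, 4 libraries) or a non-targeting hairpin (shNT, 2 libraries). LAMP5 encodes a member of the lysosome-associated membrane protein family. The series title names inflammatory signalling and MLL-rearranged leukaemia, and the comparison asks which transcripts differ when LAMP5 is knocked down. Between 12192 and 12661 rows reached 1 TPM in each library. Read depth is unknown.

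LAMP5 (ENSG00000125869) measured 170 and 282 TPM in shNT 1 and shNT 2, and 80.6, 65.6, 68.8 and 86.7 TPM in shLAMP5 1 to 4. The means were 226 ± 79.4 TPM (SD, n = 2) and 75.4 ± 9.89 TPM (SD, n = 4), so that shLAMP5 held 33.3% of the shNT mean. All 4 shLAMP5 libraries lay below both shNT libraries, in the direction of their labels. The log2 fold change was -1.54 (SE 0.25, 95% interval -2.11 to -0.96), with a limma p of 0.000275 before adjustment and 0.252 after Benjamini-Hochberg adjustment over all genes. The exact two-sided permutation p was 0.0667, the smallest that 15 splits allow. Of the other family members, LAMP1 (log2 fold change 0.58, limma adjusted p 0.674) and LAMP2 (0.36, adjusted p 0.833) did not pass the test, and LAMP3 stayed at or below 0.184 TPM in every library and was not tested.

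**Figure D1:**
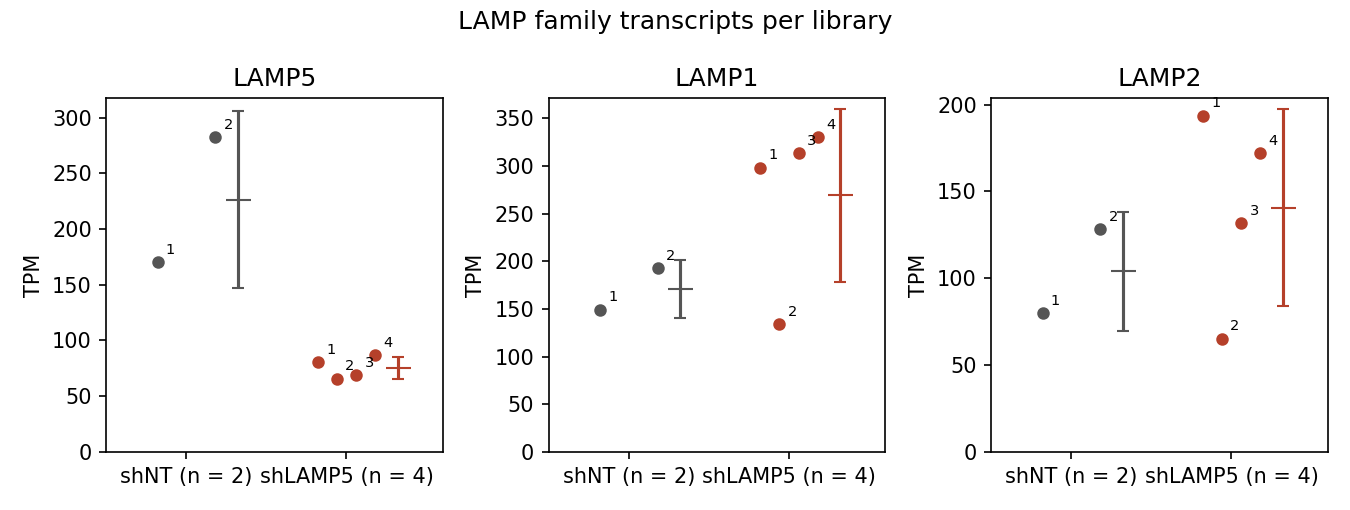
TPM of LAMP5, LAMP1 and LAMP2 in each library; points are libraries labelled by replicate number, bars are the mean and SD of shNT (n = 2) and shLAMP5 (n = 4). LAMP5 lay between 65.6 and 86.7 TPM in the shLAMP5 libraries and at 170 and 282 TPM in the shNT libraries.

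Across the 13072 genes tested, no gene passed an adjusted p of 0.05 with limma, either higher or lower in shLAMP5, and the smallest adjusted p was 0.252. At an unadjusted p under 0.05 there were 486 genes higher and 686 lower, where chance gives 654 in all on average. Genes vary together, and another split of the libraries gave up to 2970. Under median scaling that split was 845 higher and 723 lower, and without shLAMP5 2 it was 1350 higher and 903 lower. All 4 shLAMP5 libraries lay above both shNT libraries for 1079 genes and below both for 1771, together 21.8% of genes. The average over all splits is 13.3%, but a single split can lie far from it, and the share was not computed for the other splits. These counts used unscaled TPM, and the median scaling factor of shLAMP5 2 was 0.8125, against 1.003 to 1.067 in the other libraries. The unadjusted count depended on single libraries: the total of 1172 became 498 without shNT 1, 412 without shNT 2 and 2253 without shLAMP5 2. With library weights estimated from the data, added after the data were seen, 116 genes were called higher and 94 lower, but 1 other split of the libraries then gave 2422 calls. Libraries of a group differed: the Spearman correlation across genes, which are not independent replicates, was between 0.928 and 0.942 for shLAMP5 2 with the other shLAMP5 libraries, against 0.956 to 0.986 among the other 3. Pairs across the groups could be as close: shNT 2 correlated at 0.979 with shLAMP5 1 and 0.973 with shLAMP5 4, and at 0.972 with shNT 1. The closest library to shLAMP5 2 was shNT 1 (0.957). On the first principal component, the axis of largest variance (45.4%), shNT 1, shLAMP5 2 and shLAMP5 3 had the opposite sign to shNT 2, shLAMP5 1 and shLAMP5 4.

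Proliferation genes were lower in the shLAMP5 libraries. Of 41 cell cycle genes, all 41 had a negative log2 fold change, with a median of -0.96, and 40 were lower in all 4 shLAMP5 libraries than in both shNT libraries. Adjusted over the list alone, 36 of them passed the test, and over all genes 0 did. AURKA, a mitotic kinase, measured 51.6 ± 4.03 TPM in shNT (SD, n = 2) and 24.4 ± 2.57 in shLAMP5 (SD, n = 4), a log2 fold change of -1.05. TOP2A, the topoisomerase of dividing cells, had a log2 fold change of -1.35. The mean of the list was 5.63 and 5.62 on the log2(TPM + 1) scale in shNT 1 and 2, and 5.03, 4.73, 4.09 and 4.77 in shLAMP5 1 to 4. The camera test called the list lower (adjusted p 1.18e-29 at the preset correlation), a call lost with an estimated correlation (adjusted p 0.443), and the exact permutation p of the list mean was 0.0667.

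All 31 MYC target genes tested also had negative values, with a median log2 fold change of -0.57, and 24 of them were lower in all 4 shLAMP5 libraries than in both shNT libraries. Adjusted over the list alone, 3 passed, and over all genes 0 did. SRM, spermidine synthase, measured 244 ± 11.2 TPM in shNT and 90.4 ± 11.0 TPM in shLAMP5 (log2 fold change -1.43, limma adjusted p 0.252). HSPD1, a mitochondrial chaperonin that is a member of both the MYC and the heat shock list, had a log2 fold change of -1.34 (limma adjusted p 0.252). Camera called the MYC list lower (adjusted p 3.16e-14), with an adjusted p of 0.443 with an estimated correlation, and the exact permutation p of the list mean was 0.133. Of 17 heat shock genes, 16 had negative values, with a median of -0.49 (camera adjusted p 7.04e-05, and adjusted p 0.443 with an estimated correlation). HSPD1 passed over the heat shock list alone. The co-chaperone STIP1 had a log2 fold change of -0.57, and the inducible chaperone HSPA6 was the 1 positive member, at 1.01, or 0.28 without shNT 2 and 1.73 without shNT 1. Neither passed the test.

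Markers of monocyte and macrophage differentiation were higher in the shLAMP5 libraries, with positive values for 20 of 21 genes and a median log2 fold change of 0.93, and 7 of the 21 were higher in all 4 shLAMP5 libraries than in both shNT libraries. Only 21 of 27 members of the list were tested, since the rest were too low. The list mean was 4.92 and 4.75 in shNT 1 and 2, 5.16 in shLAMP5 2 and between 5.59 and 6.30 in the other shLAMP5 libraries. In shLAMP5 2 the members LYZ, S100A8 and S100A9, named after their values were seen, lay below both shNT libraries, at 1397, 27.3 and 54.1 TPM. CSF3R, the receptor of granulocyte colony-stimulating factor, measured 104 ± 11.3 TPM in shNT (SD, n = 2) and 222 ± 9.52 TPM in shLAMP5 (SD, n = 4), a log2 fold change of 1.09, and passed over the list alone as the 1 member to do so. TYROBP, a signalling adaptor of myeloid receptors, had a log2 fold change of 1.21 and KLF4, a transcription factor of monocytes, -0.094. Camera called the list higher (adjusted p 1.47e-08), with an adjusted p of 0.443 with an estimated correlation. The median became 0.58 without shNT 2.

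Of 41 lysosome genes, 37 had positive values, with a median log2 fold change of 0.55, and 14 were higher in all 4 shLAMP5 libraries than in both shNT libraries. None passed over the list alone or over all genes. The protease genes CTSD and CTSF had log2 fold changes of 1.33 and 1.19, and ATP6V0D1, a subunit of the lysosomal proton pump, and NAGLU had -0.57 and -0.15. The list was called higher by camera (adjusted p 3.01e-11), with an adjusted p of 0.572 with an estimated correlation. The mean of the list in shLAMP5 2, 5.14, lay within the shNT values of 5.06 and 5.15, while the other shLAMP5 libraries lay between 5.69 and 5.98. Autophagy genes had a smaller median of 0.14, with 27 of 38 positive (camera adjusted p 0.00911, and adjusted p 0.692 with an estimated correlation). GABARAPL1 and MAP1LC3A, of the family that coats autophagosomes, had log2 fold changes of 1.16 and 0.85, ATG5 and ATG16L1 had -0.29 and -0.20, and none passed. The autophagy median ranged from 0.071 without shNT 1 to 0.26 without shLAMP5 2.

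Among MHC class II presentation genes, 6 of 7 had positive values and the median was 0.48 (camera adjusted p 0.0176, and adjusted p 0.443 with an estimated correlation). CTSS, which trims the invariant chain and is also in the lysosome list, had a log2 fold change of 0.69, HLA-DMB 0.55 and HLA-DOB -0.63, none past the test. HLA-DMB lay at or below 1.121 TPM in every library, and only 7 of 15 members of the list were tested. The call was lost without shNT 2 (median 0.43, adjusted p 0.0682) and with no filter on low genes (0.037).

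**Figure D2:**
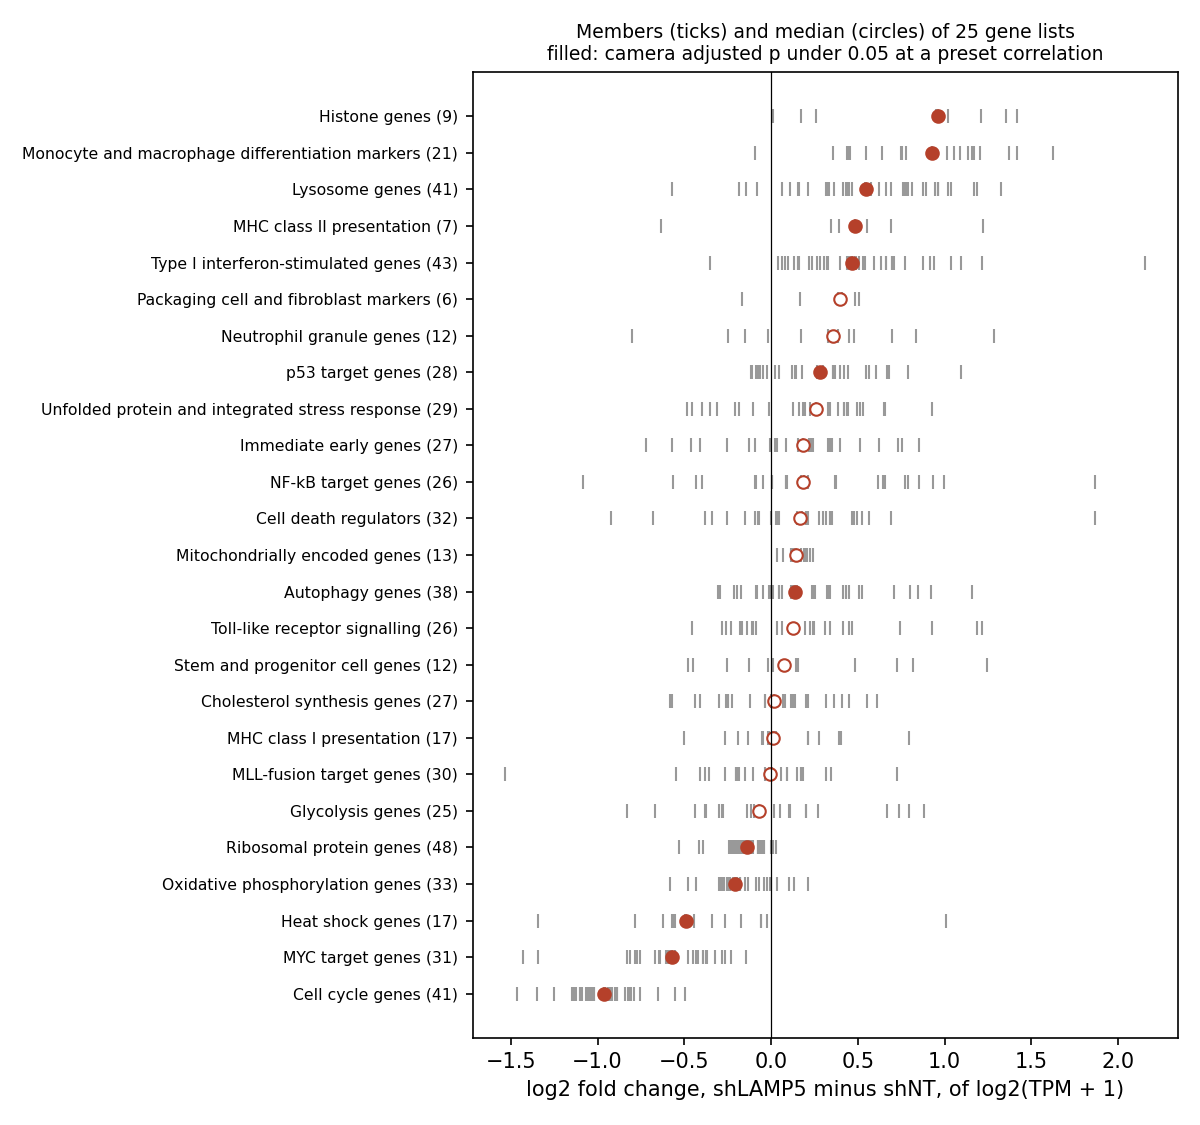
Log2 fold change (shLAMP5 minus shNT, of log2(TPM + 1)) of the members of 25 gene lists; ticks are genes, circles are list medians, filled where camera gave an adjusted p under 0.05 at the preset correlation, and the number of genes tested is in brackets. Every member of the cell cycle and MYC lists lay below 0, and 20 of 21 monocyte and macrophage markers lay above 0; no list passed with an estimated correlation.

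Genes of inflammatory signalling were mixed. Of 43 type I interferon-stimulated genes, 42 had positive values with a median log2 fold change of 0.47, and camera called the list higher (adjusted p 1.54e-07), with an adjusted p of 0.572 with an estimated correlation. IFI6 measured 15.6 ± 6.82 TPM in shNT (SD, n = 2) and 72.5 ± 22.1 TPM in shLAMP5 (SD, n = 4), a log2 fold change of 2.16, and was the 1 member that passed over the list alone. IFI35 had a log2 fold change of 0.77, HERC5 -0.35 and IRF7, a transcription factor of the interferon response, 0.53, none past the test. The list mean on the log2(TPM + 1) scale was 3.36 and 2.30 in shNT 1 and 2, a gap of 1.06, while the groups differed by 0.51. Without shNT 2 the median was 0.15 and the call was lost (adjusted p 0.322), and without shNT 1 it was 0.96.

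NF-kB target genes, with 19 of 26 positive and a median of 0.18, were not called (camera adjusted p 0.0625, and adjusted p 0.720 with an estimated correlation). BCL2A1, an anti-apoptotic member of the BCL2 family, had a log2 fold change of 1.87 (1.00 without shNT 2 and 2.73 without shNT 1), TNFAIP2 0.79, NFKBIB -0.40 and TNF -0.56. The inhibitors NFKBIA and TNFAIP3 had 0.37 and -0.085, and NFKBIA had 0.031 without shNT 2 and 0.71 without shNT 1. None of these genes passed the test. The NF-kB median was -0.13 without shNT 2 (adjusted p 0.854) and 0.29 without shNT 1, where the list was called (adjusted p 3.58e-05). It was also called without shLAMP5 1 (0.16, adjusted p 0.0164), without shLAMP5 4 (0.14, adjusted p 0.026), without shNT 1 and shLAMP5 2 together (0.34, adjusted p 0.00371), at a minimum of 10 TPM (0.37, adjusted p 0.00263) and with protein-coding rows only (0.18, adjusted p 0.045). Toll-like receptor signalling genes were not called either, with a median of 0.13 (camera adjusted p 0.11, and adjusted p 0.720 with an estimated correlation). At the preset correlation they were called without shLAMP5 2 (0.26, adjusted p 0.0341) and with library weights (0.23, adjusted p 0.0419). TLR4 and its co-receptor LY96 had log2 fold changes of 1.21 and 0.93, CHUK and IRF8 had -0.28 and -0.46, and none passed.

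**Figure D3:**
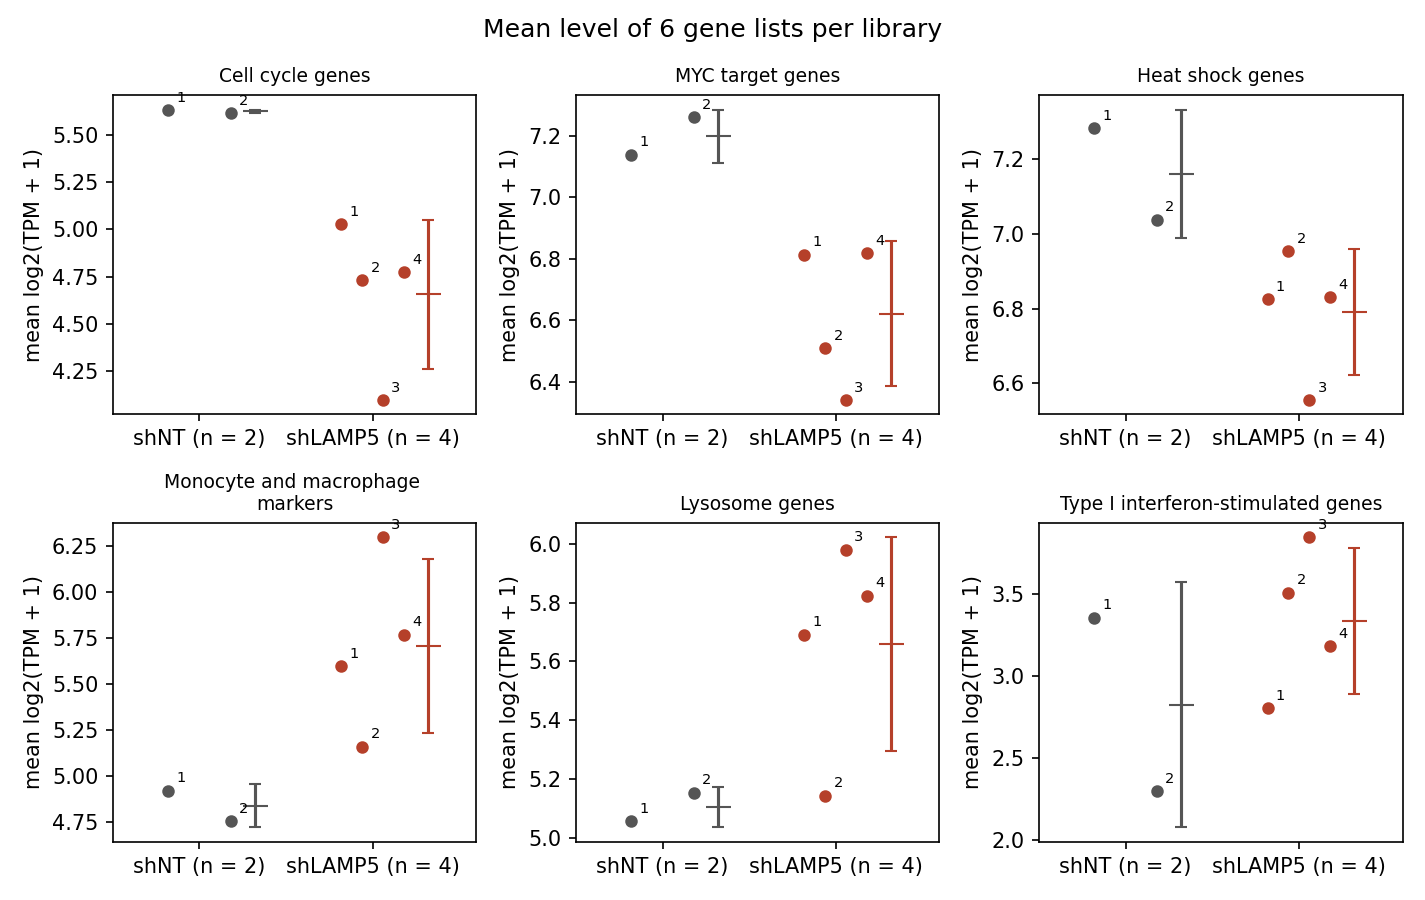
Mean log2(TPM + 1) of 6 gene lists in each library; points are libraries labelled by replicate number, bars are the mean and SD of shNT (n = 2) and shLAMP5 (n = 4). Cell cycle means were 5.63 and 5.62 in shNT and between 4.09 and 5.03 in shLAMP5, while the interferon list was at 3.36 in shNT 1 and 2.30 in shNT 2.

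MLL-fusion target genes had a median log2 fold change near 0 (-0.0055, 13 of 30 positive, and 0.021 under quantile normalization and 0.059 under median scaling) and were not called (camera adjusted p 0.671). LAMP5 is itself a member of this list, and was the 1 gene that passed over the list alone. HOXA9 and MEIS1, the transcription factors that MLL fusions maintain, had log2 fold changes of 0.31 and -0.20, LMO2 0.72, ZEB2 0.34 and ADGRA3 -0.55, and none passed.

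The p53 target genes had positive values in 21 of 28 and a median of 0.28 (camera adjusted p 0.0031, and adjusted p 0.720 with an estimated correlation). FAS and TP53INP1 had log2 fold changes of 0.79 and 1.09, POLH and PPM1D -0.12 and -0.11, none past the test. The p53 call was lost without shNT 1 (median 0.16, adjusted p 0.153) and without shNT 1 and shLAMP5 2 together (0.27, adjusted p 0.0769), and the median was 0.14 without shLAMP5 3. Cell death regulators were not called (median 0.16, camera adjusted p 0.107), with a median of 0.049 without shLAMP5 3 and 0.28 without shLAMP5 2. CASP1 had a log2 fold change of 0.47 and BIRC5, which also serves mitosis, -0.92, and neither passed the test.

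All 9 histone genes had positive values, with a median of 0.96 (camera adjusted p 0.00152, and adjusted p 0.635 with an estimated correlation). H2BC12 had a log2 fold change of 1.02 and H1-2 1.41 (0.68 without shNT 2 and 2.15 without shNT 1). The histone call was lost without shNT 2 (median 0.35, adjusted p 0.221) and without shLAMP5 2 (0.74, adjusted p 0.287), the library with the highest list mean, and with library weights (0.46). The median was 1.54 without shNT 1.

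Ribosomal protein genes were lower by a small amount, with 46 of 48 negative and a median of -0.14 (camera adjusted p 0.00387, and adjusted p 0.720 with an estimated correlation). This call was lost under quantile normalization (median -0.082, adjusted p 0.0885), without shNT 1 (-0.085, adjusted p 0.272) and without shLAMP5 1 (-0.11, adjusted p 0.122), and the median was -0.072 under median scaling. Oxidative phosphorylation genes had a median of -0.21, with 29 of 33 negative (camera adjusted p 0.0213, and adjusted p 0.720 with an estimated correlation). That call was lost under quantile normalization (-0.14, adjusted p 0.107), at a minimum of 10 TPM (adjusted p 0.0795), with library weights (-0.026), without shNT 2 (-0.084, adjusted p 0.530), without shLAMP5 2 (-0.083, adjusted p 0.287) and without shLAMP5 3 (-0.18, adjusted p 0.104).

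In all, camera at the preset correlation called 12 of 25 lists, 7 higher and 5 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.443, and fry called 0, with a smallest adjusted p of 0.148. The exact permutation p of the list mean was 0.0667 for the cell cycle, heat shock and MHC class II lists. It was 0.133 for the MYC, monocyte and macrophage, and ribosomal lists, 0.2 for lysosome, 0.267 for p53, 0.333 for autophagy and histone, 0.4 for interferon-stimulated and 0.533 for oxidative phosphorylation genes. The lists not called also included mitochondrially encoded genes (median 0.14), neutrophil granule genes (0.36), stem and progenitor genes (0.076), glycolysis (-0.072), cholesterol synthesis (0.017), the unfolded protein and integrated stress response (0.26), MHC class I presentation (0.0096), immediate early genes (0.19) and packaging cell and fibroblast markers (0.40). Some of these were called higher once 1 library was left out. Neutrophil granule genes were called without shNT 2 (0.41, adjusted p 0.0332) and without shLAMP5 2 (0.55, adjusted p 0.0187). Mitochondrially encoded genes were called without shLAMP5 3 (0.26, adjusted p 0.00157) and without shLAMP5 4 (0.20, adjusted p 0.0297), the unfolded protein response without shNT 1 (0.49, adjusted p 0.000205) and without shLAMP5 4 (0.36, adjusted p 0.00249), and immediate early genes without shNT 1 (0.35, adjusted p 0.0222) and without shLAMP5 1 (0.41, adjusted p 0.0229). The packaging cell and fibroblast median was 0.050 without shNT 2, and the mitochondrially encoded median was 0.017 without shLAMP5 2.

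The genes with the smallest p-values, chosen after their values were seen, included, among those lower in shLAMP5, LAMP5, AURKA, SRM and HSPD1, given above, MPDU1, which serves glycosylation in the endoplasmic reticulum, with 32 ± 0.438 TPM in shNT and 7.56 ± 2.38 in shLAMP5 (log2 fold change -1.99), and NME4, a mitochondrial nucleoside diphosphate kinase (-1.78). Among those with higher values were IFI6, CSF3R and TSPAN32, a tetraspanin of blood cells, with 5.39 ± 0.348 TPM in shNT and 16.6 ± 3.84 in shLAMP5 (1.44). The limma adjusted p of each of these but AURKA was 0.252.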

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

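The tests of explanations in this part were chosen after the results were seen. A first test for RNA of other cells in the interferon pattern was left out after its value was seen, because it set together libraries picked by that same outcome, and the test of library scaling took its place. A test of LAMP5 knockdown as the cause of that pattern was also left out, because the design fixed its outcome. The minimum of 10 small RNA genes was also set after the value was known.

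Among the 4 shLAMP5 libraries, shLAMP5 2 lay far from the others, by Dixon's test, in 4 of 80 results tested. Chance flags about 1 in 20 results for any of the 4 libraries, which gives about as many flags as were found. All 4 flags here fell on shLAMP5 2, but the 80 results overlap and come from the same libraries, so the flags are not independent. The mean of Toll-like receptor signalling genes was 3.44 on the log2(TPM + 1) scale in shLAMP5 2, against 3.97 to 4.01 in the others. The mean of MHC class I presentation genes was 4.21, against 4.61 to 4.67. LAMP1 was at 7.08 on the log2(TPM + 1) scale (134 TPM, against 298 to 330 TPM), and LMO2 at 6.29 (77.4 TPM, against 139 to 150 TPM).

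Cell cycle genes were lower in shLAMP5. Library scaling as the whole cause is argued against by the median scaling factors. They were 1.003 and 1.058 in shNT and between 0.8125 and 1.067 in shLAMP5, which differ too little to make a list median of -0.96. That median stayed at -0.89 or lower under quantile normalization and median scaling, but factors of this size largely fixed that outcome, so it adds no further evidence. The library shLAMP5 2 alone is argued against by the median of -0.999 without it. What stays open is an effect of LAMP5 knockdown, an off-target effect of a hairpin, and a difference in harvest time or culture density. These cannot be told apart, because 0 libraries have labels that state a hairpin or a harvest time. The titles number the libraries without saying whether the number marks a replicate or a hairpin.

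Interferon-induced genes varied within the groups. Of 43 genes in the list, 37 were higher in shNT 1 than in shNT 2, and IFIT1, chosen after its values were seen, measured 20.9 and 0.495 TPM there, against 0.706, 17.4, 13.9 and 1.89 TPM in shLAMP5 1 to 4. The list mean differed by 1.06 between the shNT libraries and by 0.51 between the groups. Library scaling is argued against by the median scaling factors of shNT 1 and shNT 2, 1.003 and 1.058, which differ too little to make such a gap. The median gap between the shNT libraries was 0.963 after median scaling, but those factors fixed that outcome, so it adds no further evidence. A response to transduction or to culture that differed between libraries may account for it and was not tested.

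The library shLAMP5 2 stood apart from the rest of its group. One row with no symbol in the reference, ENSG00000226958, held 7.26% of its summed TPM, but rescaling by that row leaves ranks unchanged, and the highest Spearman correlation of shLAMP5 2 with another shLAMP5 library was 0.942, below the lowest among the others (0.956). More non-polyadenylated RNA stays open. Small RNA genes were 1.43 higher in shLAMP5 2 than in the other 3, though only 2 could be tested, and the 9 histone genes had a median 0.84 higher. Both values lay above the bound first set. Whether the histone transcripts counted here lacked a poly(A) tail is unknown, so the histone value cannot decide this. Its members differed: H4C3 measured 35.0 TPM in shLAMP5 2, against 2.52, 3.15 and 1.87 TPM in shLAMP5 1, 3 and 4. H2BC12 measured 152 TPM, against 138, 246 and 192 TPM. Both were picked after their values were seen. A response to low oxygen also stays open, since the median of 17 hypoxia markers was 0.23 higher and 10 of them were higher. MIR210HG, a transcript induced by low oxygen, is 1 of those 17 and had the largest difference of them (5.325). It was chosen after its values were seen, and measured 51.6 TPM in shLAMP5 2, 7.86 TPM in shNT 1 and at most 0.597 TPM in the other 4 libraries. Other markers that were higher in shLAMP5 2 included ANGPTL4 (3.42), ENO2 (2.83), ADM (2.03) and ALDOC (1.82). Markers that were lower in shLAMP5 2 included PGK1 (-0.57), LDHA (-0.44), NDRG1 (-0.32) and PDK1 (-0.29). These were also named after their values were seen. Mitochondrially encoded genes summed to 126549 TPM in shLAMP5 2, against 79300 to 99704 TPM in the other libraries. Fewer rows lay above 0 in it (20325, against 21610 to 22635), though more reached 1 TPM (12661, against 12192 to 12579). Whether the quality of its RNA or library differed was not tested.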

How the results depend on the processing

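Library weights, protein-coding rows only, and leaving out shNT 1 with shLAMP5 2 were tried after the data were seen, and the other settings were planned. The direction of cell cycle, MYC target, heat shock, lysosome, and monocyte and macrophage genes, and their camera calls at the preset correlation, held in every setting that refitted the genes, and LAMP5 was lower in each. With an estimated correlation 0 lists were called, and with fry 0. Without a filter, 14 rows were called lower, all low and listed at 0 in every shLAMP5 library. Some of these rows held identical values, so they are not 14 separate genes. The MHC class II median was 0.037 there and not called. At 10 TPM or more the Toll-like receptor median was -0.089, and the oxidative phosphorylation median was -0.21 and not called; NF-kB targets (0.37) and mitochondrially encoded genes (0.14) were called there, and MHC class II genes gave no value. Quantile normalization gave 0.021 for MLL-fusion targets, and -0.082 for ribosomal and -0.14 for oxidative phosphorylation genes, neither called. Median scaling gave 0.059 for MLL-fusion targets. With library weights, 116 genes were higher and 94 lower, LAMP5 passed at -1.40, Toll-like receptor genes were called (0.23), oxidative phosphorylation (-0.026) and histone (0.46) genes were not called, and signs turned for MLL-fusion targets (0.012), the unfolded protein response (-0.082), immediate early genes (-0.073), IRF7 (-0.13) and KLF4 (0.0031). Without shNT 1 and shLAMP5 2, p53 targets were not called (0.27), NF-kB targets were (0.34), and signs turned for MLL-fusion targets (0.041), mitochondrially encoded (-0.065), glycolysis (0.036) and cholesterol genes (-0.11), TNFAIP3 (0.17), HERC5 (0.20) and KLF4 (0.15). The cause was not tested.

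Shared replicate numbers do not pair the libraries: the deviations of same-numbered libraries correlated at -0.52 and -0.47, and the labels give no shared batch. With 2 shNT libraries, each deviates by the opposite of the other. Libraries with unlike numbers also correlated positively: shNT 1 at 0.474 with shLAMP5 2 and 0.276 with shLAMP5 3. Likewise shNT 2 reached 0.52 with shLAMP5 1 and 0.518 with shLAMP5 4, and the opposite shNT library gave each value with a negative sign. Such variation across the groups has no term in the main test. With the replicate block, 9 genes were higher and 10 lower in the 4 libraries that share numbers, and 7 and 9 in all 6, against 0 and 0 in the 4 without the block. In the fit to all 6, shLAMP5 3 and shLAMP5 4 are each alone in their block and add nothing to the group difference. Both block fits therefore rest on the same 4 libraries, gave the same list medians, and are not separate evidence. Their calls included UQCR11 (-2.595 in both), which was listed at 0 in shLAMP5 2. Both block fits gave 0.10 for p53 targets and -0.17 for ribosomal genes, neither called, while the 4 libraries without the block kept both calls. Toll-like receptor (-0.011) and MHC class I genes (-0.061) turned sign with and without the block. The block fits also called NF-kB targets (0.052), mitochondrially encoded (0.39), cholesterol (0.15), unfolded protein response (0.38) and immediate early genes (0.29), and the 4 libraries without the block called all of these but NF-kB targets.

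Leaving out 1 library at a time gave ranges of -0.060 to 0.039 for MLL-fusion targets, -0.13 to 0.29 for NF-kB targets, 0.15 to 0.96 for interferon-stimulated genes, -0.079 to 0.26 for Toll-like receptor genes, -0.064 to 0.16 for stem cell genes, 0.14 to 0.38 for p53 targets, -0.19 to -0.085 for ribosomal genes, -0.34 to -0.083 for oxidative phosphorylation, -0.15 to 0.015 for glycolysis, -0.12 to 0.19 for cholesterol synthesis, -0.089 to 0.49 for the unfolded protein response, 0.0034 to 0.55 for neutrophil granule genes, 0.017 to 0.26 for mitochondrially encoded genes, 0.049 to 0.28 for cell death regulators, 0.050 to 0.56 for packaging cell and fibroblast markers, -0.054 to 0.19 for MHC class I, 0.43 to 0.59 for MHC class II, -0.071 to 0.41 for immediate early genes and 0.35 to 1.54 for histones. Gene ranges were -0.45 to 0.28 for TNFAIP3, -0.32 to 1.38 for IRF7, -1.32 to 0.62 for HERC5, -0.43 to 0.24 for KLF4, -0.25 to 0.032 for PPM1D, 0.40 to 0.88 for LAMP1, 0.021 to 0.70 for LAMP2, 0.19 to 0.40 for HOXA9, -0.37 to -0.027 for MEIS1, -0.80 to -0.11 for IRF8, -0.36 to -0.18 for CHUK, -0.21 to -0.020 for POLH, -0.98 to -0.29 for HLA-DOB, -0.27 to -0.027 for NAGLU, -0.86 to -0.26 for TNF and 0.21 to 0.48 for ZEB2. With an shNT library left out, the remaining one is assumed to vary like the others. Planned tests on read counts and on single transcripts were not run, because the table holds TPM per gene, and unknown depth limits what can be said of low genes.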

Other observations

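The tests of other splits and the weighted fit in this part were chosen after the results were seen. With library weights, which gave shLAMP5 2 a weight of 0.193 and shLAMP5 4 a weight of 3.41, limma called 210 genes. They included 10 cell cycle and 3 MYC target genes, all lower, and 10 lysosome and 4 monocyte and macrophage genes, all higher. Some called rows held identical values, such as HLA-E and ENSG00000225201, so 210 overstates the number of separate genes. Under the rule for named genes, which keeps genes at or above the median expression with all 4 shLAMP5 libraries on 1 side of both shNT libraries, the 12 with the largest decrease included FOXM1, a transcription factor of mitotic genes (38.5 ± 3.89 TPM in shNT, 13.4 ± 3.76 in shLAMP5), and the replication genes MCM2 and ORC1. The 12 with the largest increase under that rule included CD68, a macrophage glycoprotein (85.2 ± 0.011 and 204 ± 71.4 TPM), FCER1G, TYROBP and FGR, which signal in myeloid cells, and PLD3, a lysosomal protein. These calls rest on the weights, since the unweighted test called 0 genes.

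LYZ, the secreted enzyme lysozyme, measured 1984 and 6062 TPM in shNT 1 and 2, and 9730, 1397, 5119 and 9415 TPM in shLAMP5 1 to 4. HMOX1, which degrades haem, measured 59.2 and 7.89 TPM, and 55.9, 321, 212 and 27.6 TPM. These genes were chosen after their values were seen.

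Chance was set against the real grouping by refitting all 15 splits of the 6 libraries into 2 and 4, which cannot give a share under 0.05. The real split gave 1172 genes at an unadjusted p under 0.05, the highest other split gave 2970, and 3 of the 15 splits, the real one included, gave as many. It called 12 lists, the highest other split called 14, and 7 of the 15, the real one included, called as many. The split with 2970 genes set shLAMP5 2 and 3 against the rest, and with library weights the split of shLAMP5 1 and 4 gave 2422 calls against 210, which points to a structure of the samples other than the groups.

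Summed TPM of T cell markers was between 53 and 322 per library. IL7R reached the highest value of a member (254 TPM in shLAMP5 3), while CD4, which monocytic cells also express, was above IL7R in shNT 2, shLAMP5 1 and shLAMP5 4 (38.5, 44.5 and 56.8 TPM). The sum of B cell markers was at most 4.31. Erythroid markers summed to between 74.1 and 150 TPM, with TFRC, which dividing cells also express, as the highest member, and megakaryocyte markers to between 15.6 and 23.0. IL7R, CD4 and TFRC were named after their values were seen. PRKCSH and UQCR11, chosen after their values were seen, were listed at 0 in shLAMP5 2 and above 4.9 TPM in the other libraries, which can be a failed estimate.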
